A study of Mus musculus with 16 samples.

How the data were processed

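RNA was measured in RAW264.7 cells, a mouse macrophage-like line, kept for 24 h in 4 conditions: vehicle (ethanol, 0.1% by volume), docosahexaenoyl serotonin (DHA5HT, a conjugate of an n-3 fatty acid with serotonin) at 1 µM, lipopolysaccharide (LPS, a component of the bacterial cell wall) at 1 µg/ml, or LPS with DHA5HT. The labels name ethanol for the control arrays only, so the vehicle may differ between the groups compared. Per the labels, 100 ng of total RNA with an RNA integrity number above 8 went onto each Affymetrix whole-transcript array. The deposited values are on a log2 scale and come from RMA per the submitters' processing notes, which means background correction, normalization between arrays and 1 summary value per probe set. The version of RMA was not given in the sources used here, and neither were the array annotation the authors used and any filter. The value table held 35556 probe sets for 16 arrays with no missing value, from 1.20 to 13.68. Array medians lay between 4.58 and 4.67 and upper quartiles between 7.60 and 7.67.

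Probe sets were joined to genes through the array's gene table. Of the 35556 probe sets, 21218 named exactly 1 gene, 1881 named several and 12457 were not in that table. Where a gene had several probe sets (1386 genes), the one with the highest mean over all 16 arrays was used, which left 18820 genes. The gene identifier was found in the RefSeq gene table for 18790 of them, and 17894 were protein coding. No genome build was named for the values, so no positions are given.

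Groups followed the sample titles. For array 1 of the LPS with DHA5HT group the title names both agents while the treatment label names DHA5HT alone. The title was followed, and each count was also computed without that array. The labels do not say whether the 4 arrays of a group came from separate cultures, so the p values measure only the spread between these samples, and the number of arrays limits their precision.

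Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 group means over all 16 arrays, 12 residual degrees of freedom, two-sided). The Benjamini-Hochberg adjustment ran over the 18820 genes within each comparison, with a threshold of 0.05. There were 4 comparisons: LPS against control, DHA5HT in LPS-treated cells, DHA5HT without LPS, and the difference between these DHA5HT effects. The relation between the LPS response and the DHA5HT effect in LPS-treated cells was measured across genes against the LPS main effect (the mean of the LPS-treated groups minus the mean of the others), which shares no error with that DHA5HT effect when groups have equal size. Its chance level came from the 35 splits of 8 arrays into 4 and 4.

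There were 34 gene lists with 745 members, 674 of them measured. Each was tested with limma's camera (preset correlation between genes of 0.01), adjusted over the 34 lists within a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list moved on balance in one direction, were run beside it. For each list the number of genes past the threshold is also given when adjusted over the list alone.

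Genes were named by a rule. In the first 3 comparisons it took the 12 largest increases and the 12 largest decreases among genes past the threshold whose 4 arrays of one group all lay above the 4 of the other. It also took up to 4 members with the smallest p from each list that passed and from the IL-23 and IL-17 lists. In every comparison it took Il23a, Il12b, Il6, Il1b, Tnf, Nos2, Ptgs2, Ccl2, Ccl20, Cxcl10, Il10, Csf3 and Mmp9. Predicted genes, microRNAs, small nucleolar RNAs and receptor families of smell and pheromones were counted but not named under the first part. Groups, comparisons, tests, lists, this rule and the alternative settings were fixed before the data were examined.

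The alternatives were a replicate block, an intensity trend in eBayes, a filter keeping genes brighter than the median gene, quantile normalization applied again, centring of each array on its median, all probe sets in place of 1 per gene, array weights, other thresholds, a fit on the compared arrays alone, the other list tests, and leaving out each array of the compared groups in turn. The procedure was tested on simulated data with 100 genes changed by 0.5 and 100 by 1 on the log2 scale among 18820. It recovered 82%, 74%, 83% and 43% of the smaller changes and 99%, 99%, 98% and 92% of the larger ones, in the order of the comparisons above. False calls made up 8.12%, 3.35%, 4.74% and 4.93% of all calls. The simulated genes varied independently and same-numbered arrays shared nothing, so these rates do not cover genes or arrays that vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets with several genes or none were left out of the comparisons, and the cause of the label conflict could not be settled from the labels.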

Results

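Transcripts of 18820 genes were measured on 16 arrays of RAW264.7 macrophages, 4 each of vehicle control, DHA5HT, LPS and LPS with DHA5HT (written LPS+DHA5HT). All values are log2 intensities, and errors are SD with n = 4 unless an SE is named. The first principal component held 70.6% of the variance and the second 4.72%. On the second, LPS+DHA5HT array 4 stood at 22.4 and the other arrays at no more than 9.36. The array with conflicting labels (LPS+DHA5HT array 1) was placed between the control mean (0%) and the LPS mean (100%) over 136 genes changed at least 4-fold by LPS. Its median position was 83.8%, against 78.5% to 90.8% for the other LPS+DHA5HT arrays and −4.41% to −1.41% for the DHA5HT arrays. Markers of lymphocytes and epithelial cells had a median of 3.77, which serves as a level for genes that macrophages should lack, and the median gene lay at 5.23. Where a gene's mean lies below 3.77 in a group, its change against that group is a lower bound, and where it lies below 3.77 in both groups the change is between values not above background.

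LPS against control asks how the cells responded to the bacterial stimulus. Among the genes named by the rule, the inflammatory cytokine genes Il1a, Il1b and Il6 rose most. Il6, a cytokine of the acute phase response, went from 3.12 ± 0.12 (SD, n = 4) to 11.01 ± 0.12 (SD, n = 4), at least 237-fold higher, and Il1b, which encodes interleukin-1 beta, went from 4.42 ± 0.25 to 12.52 ± 0.05, 275-fold higher. Il1a, like Il6 below 3.77 in controls, rose by at least 8.81 (SE 0.23), the siderophore-binding protein gene Lcn2 by 7.58, the acute phase gene Saa3 by 7.56 and the growth factor genes Csf2 and Csf3 by 5.76 each. Genes that fell included Cx3cr1, the fractalkine receptor (−3.52), Tgfbi (−3.24), the flagellin receptor Tlr5 (−2.64) and the chemokine receptors Cxcr4 (−2.50) and Cxcr3 (−2.17). Of the 18820 genes, 5346 changed (limma, adjusted p under 0.05), 2376 higher and 2970 lower, and 363 rose and 268 fell at least 2-fold.

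The IL-23 axis is named in the study's title. IL-23 is a dimer of the products of Il23a and Il12b, and it sustains T cells that make IL-17. Il23a (probe set 10373358) rose from 4.70 ± 0.07 to 8.63 ± 0.21, 15.3-fold (adjusted p = 8.7e-14), and Il12b (probe set 10375331) from 4.30 ± 0.21 to 8.25 ± 0.18, 15.5-fold (adjusted p = 2.05e-11). Jak2, a kinase that signals from the IL-23 receptor, rose by 2.33 and Ebi3, a subunit of IL-27, by 1.14. Of the 13 measured genes of the IL-23 and IL-12 list 8 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 2.19e-05, adjusted p = 0.117 with an estimated correlation). The genes that fell were the receptor chains Il12rb2 (−1.51) and Il6st (−0.26), named after their values were seen. Among 24 known IL-17 target genes 19 rose and 0 fell (19 adjusted over the list alone, camera adjusted p = 2.24e-24), among them Nfkbiz, a cofactor of NF-kB, by 2.94, Zc3h12a, an RNase that degrades cytokine transcripts, by 2.53, Ptgs2, which encodes cyclooxygenase-2, by 2.92, Ccl2 by 2.99 and Ccl20 by 0.46. The list of IL-17 cytokines, receptors and adaptors did not pass (adjusted p = 0.709), with a median change of −0.00305 and a mean of 0.06. Of its 14 measured genes the adaptor Traf3ip2 rose by 0.61 and the receptor chain Il17rc fell by 0.26 (adjusted p = 0.0358), with 1 higher and 0 lower adjusted over the list alone. The Il17rc call was lost without LPS array 1 or 4 or control array 3 or 4 (log2 change −0.26 to −0.18, adjusted p 0.0660 to 0.139), after quantile normalization (adjusted p = 0.0816) and after centring (adjusted p = 0.0799). Because the study chose these pathways on these samples, counts adjusted over the list alone are not independent evidence for them.

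Other signalling lists rose as well. Of 19 pro-inflammatory cytokines 15 rose and Il15 fell by 1.02 (15 and 1 adjusted over the list alone, camera adjusted p = 8.22e-19), with Tnf up by 1.85. Of 24 chemokines 17 rose, such as Ccl5 by 5.17, Cxcl10 by 3.50 and Ccl4 by 2.02, while Ccl24 fell by 0.41 (17 and 1 adjusted over the list alone, adjusted p = 8.17e-15). Of 24 NF-kB components and feedback regulators 19 rose, including Socs3 by 5.18 and Irak3 by 2.01, and Tnip3 fell by 0.78 (20 and 2 adjusted over the list alone, adjusted p = 2.87e-19). Of 34 interferon-stimulated genes 31 rose and 0 fell, among them the antiviral genes Oasl1 (3.15), Gbp2 (3.85) and Gbp7 (4.27), with 32 adjusted over the list alone and adjusted p = 3.1e-25 (adjusted p = 0.0566 with an estimated correlation and 0.00257 with the replicate block added to it). Nos2, the inducible nitric oxide synthase, rose from 5.29 ± 0.46 to 9.66 ± 0.28, and with it 8 of 9 genes of nitric oxide and arginine metabolism rose (8 adjusted over the list alone, adjusted p = 1.22e-10), such as the arginine transporter Slc7a2 (3.58). In the antigen presentation and co-stimulation list 13 of 22 rose, among them Cd40 (2.12), Cd80 (2.44), Cd86 (2.02) and the PD-1 ligand Cd274 (2.84), and H2-DMa (−0.23) and Cd83 (−0.39) fell (13 and 2 adjusted over the list alone, adjusted p = 6.98e-08). In the matrix remodelling list 9 of 20 rose, such as Mmp9 (2.60) and Thbs1 (2.73), and Timp2 (−0.80) and Plau (−1.24) fell (9 and 2 adjusted over the list alone, adjusted p = 0.000699, adjusted p = 0.146 with an estimated correlation). The genes that fell within these lists were named after their values were seen.

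Growth and lipid synthesis genes moved the other way. All 33 measured genes of DNA replication and the cell cycle fell, among them Mcm4 (−0.92) and Mcm6 (−0.90), subunits of the replicative helicase, and Pcna (−0.68), with 33 adjusted over the list alone (camera adjusted p = 1.64e-22, adjusted p = 0.133 with an estimated correlation). Of 21 cholesterol synthesis genes 18 fell, such as Sqle (−0.69) and Hmgcs1 (−0.62), and Sc5d rose by 0.19 (19 and 1 adjusted over the list alone, adjusted p = 9.12e-08, adjusted p = 0.136 with an estimated correlation). Of 16 fatty acid synthesis genes 9 fell, such as Acss2 (−0.65) and Fasn (−0.46), and Elovl1 rose by 0.21 (9 and 1 adjusted over the list alone, adjusted p = 0.0299, adjusted p = 0.401 with an estimated correlation). Without LPS array 2 the adjusted p of this list was 0.0502.

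Weaker list calls completed the LPS comparison. Of 30 genes of oxidative phosphorylation and the citric acid cycle 8 fell, such as Idh2 (−0.49) and Sdha (−0.27), with 8 adjusted over the list alone (adjusted p = 0.0435, adjusted p = 0.522 with an estimated correlation). That call was lost without control array 2, 3 or 4 or LPS array 2 or 3 (adjusted p 0.0505 to 0.109). Of 22 genes of the unfolded protein and integrated stress response 10 rose, such as Nupr1 (1.38) and Asns (0.64), and Edem1 fell by 0.27 (11 and 1 adjusted over the list alone, adjusted p = 0.00826, adjusted p = 0.454 with an estimated correlation). Of 22 targets of NRF2, the regulator of the oxidative stress response, 9 rose, such as the cystine transporter Slc7a11 (3.44), and Gclc (−0.48), Osgin1 (−0.61), Pgd (−0.19), Taldo1 (−0.28) and Tkt (−0.17) fell (11 and 5 adjusted over the list alone, adjusted p = 0.0393, adjusted p = 0.517 with an estimated correlation). Without LPS array 3 or 4 the adjusted p of the NRF2 list was 0.0548 and 0.0552. Of 12 anti-inflammatory genes 6 rose, such as Il1rn (2.22) and Il4ra (2.20), while Il10 (−0.43), Il1r2 (−0.64), Anxa1 (−0.25) and Lgals3 (−0.39) fell (6 and 4 adjusted over the list alone, adjusted p = 0.0389, adjusted p = 0.117 with an estimated correlation). The Il10 means of 3.61 in control and 3.18 in LPS arrays both lay below 3.77, so its change is between values not above background, and its call was lost without control array 1 (log2 change −0.37, adjusted p = 0.0543).

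In the LPS comparison 16 of the 34 lists passed (12 up, 4 down), and the other 18 had adjusted p values from 0.204 to 0.999. With an estimated correlation 6 passed, with adjusted p values from 0.00372 to 0.0162: IL-17 targets, chemokines, pro-inflammatory cytokines, nitric oxide and arginine metabolism, antigen presentation and NF-kB. Among all 18820 genes 5601 did not overlap between the groups, where chance gives 2.86%. For genes changed by LPS the balance of directions depended on centring, which gave 3043 higher and 2468 lower.

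**Figure D1:**
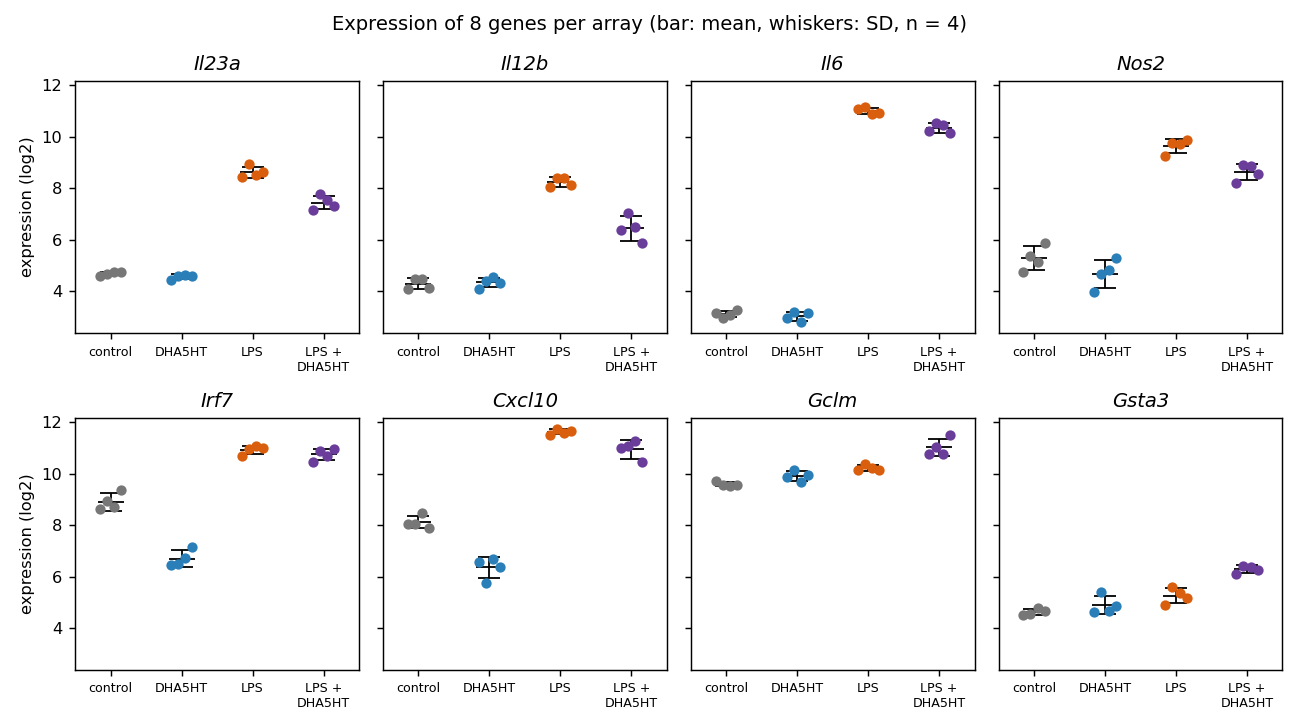
Log2 intensity of 8 genes in each of the 4 groups. Points are single arrays, bars are means and whiskers are SD (n = 4). Il23a and Il12b are raised in both LPS-treated groups and lie lower with DHA5HT there, while Irf7 and Cxcl10 lie lower with DHA5HT in cells without LPS.

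DHA5HT in LPS-treated cells is the comparison of the study's design text. DHA5HT lowered both subunit genes of IL-23. Il12b fell from 8.25 ± 0.18 (SD, n = 4) to 6.45 ± 0.48 (SD, n = 4), a change of −1.80 (SE 0.18, 3.49-fold lower, limma adjusted p = 4.62e-05), and Il23a fell from 8.63 ± 0.21 to 7.45 ± 0.27, a change of −1.18 (SE 0.12, 2.26-fold lower, adjusted p = 3.96e-05). Il6 fell from 11.01 ± 0.12 to 10.35 ± 0.19 (SE 0.10, adjusted p = 0.00278), and Csf3, the granulocyte growth factor gene, changed by −1.45 (SE 0.23, adjusted p = 0.00366). For each of these genes all 4 LPS+DHA5HT arrays lay below all 4 LPS arrays. The antioxidant genes Gclm, which encodes a subunit of the enzyme of glutathione synthesis, and Gsta3, a glutathione transferase, rose from 10.21 ± 0.11 to 11.02 ± 0.35 (adjusted p = 0.00484) and from 5.26 ± 0.30 to 6.29 ± 0.15 (adjusted p = 0.00232).

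The largest decreases were of U90926 (−2.63, SE 0.23, adjusted p = 8.48e-06) and of the small proline-rich protein genes Sprr2f (−2.21) and Sprr2e (−1.95), close relatives whose probes can share targets. The orphan nuclear receptor genes Nr4a1 (−1.87) and Nr4a3 (−1.78) fell, as did Cstdc4 (−1.64), Sprr2d (−1.63), Inhba, a subunit of activin (−1.56), and the collagenase gene Mmp13 (−1.52). The largest increase was of the protease inhibitor gene Serpinb9b (1.48, SE 0.34, adjusted p = 0.0355). Its call was kept only without LPS+DHA5HT array 1 or 3 and was lost in each of the other 6 leave-outs (1.18 to 1.55, adjusted p 0.0683 to 0.108). Treml4 rose by 1.05 (adjusted p = 0.0015) and Mgst1, a glutathione transferase of membranes, by 0.81 (adjusted p = 0.0154).

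Among the readouts of LPS activation some passed with DHA5HT and others did not, and no difference between them was tested. Tnf lost 9.39% ± 5.06 (SE) of its log2 LPS response and Il6, which passed, 8.40% ± 1.30. In LPS arrays Ptgs2, Il1b, Ccl2 and Tnf lay between 11.82 and 13.14, toward the highest value of 13.68. Whether changes are compressed at that level was not tested. Tnf (−0.17, adjusted p = 0.447), Ptgs2 (−0.15, adjusted p = 0.747), Ccl2 (−0.06, adjusted p = 0.882), Ccl20 (−0.03, adjusted p = 0.960), Il10 (−0.20, adjusted p = 0.522) and Mmp9 (0.12, adjusted p = 0.808) did not pass, and neither did Il1b (−0.50, adjusted p = 0.0848) and Cxcl10 (−0.68, adjusted p = 0.0770). Il10 lay at 2.84 to 3.29 in the LPS and LPS+DHA5HT arrays, below 3.77, so its change is between values not above background. Nos2 changed from 9.66 ± 0.28 to 8.64 ± 0.32 (−1.02, SE 0.25, adjusted p = 0.0485). The Nos2 call was kept only without LPS array 1 and was lost in each of the other 7 leave-outs (−1.11 to −0.88, adjusted p 0.0572 to 0.133).

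Of 13 genes of the IL-23 and IL-12 list 3 fell, namely Il12b, Il23a and Il27 (−0.87, adjusted p = 0.0267), with 6 lower adjusted over the list alone, which is not independent evidence since the study's title names this pathway (camera adjusted p = 1.75e-07, adjusted p = 0.121 with an estimated correlation). Without LPS array 2 or 3 or LPS+DHA5HT array 2 or 4 the Il27 call was lost (−0.86 to −0.67, adjusted p 0.0578 to 0.0910). Stat3, which transmits the IL-23 signal, did not pass (−0.25, adjusted p = 0.0507). Of 14 IL-17 cytokines, receptors and adaptors 0 passed in limma and 1 had an unadjusted p under 0.05 (1 lower adjusted over the list alone, list adjusted p = 0.454), with values of −0.22 for Traf6, −0.15 for Il17a and 0.11 for Il17f. Of 24 IL-17 target genes 4 fell, Il6, Csf3, Mmp13 and Nfkbiz (−0.47), with 8 lower adjusted over the list alone, again not independent evidence (adjusted p = 2.32e-07, adjusted p = 0.128 with an estimated correlation). Il6, Csf3, Il1b and Tnf are also members of the pro-inflammatory cytokine list, so the calls of these lists are not separate findings.

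The pro-inflammatory cytokine and NRF2 lists kept their calls with an estimated correlation. Of 19 pro-inflammatory cytokines 8 fell (11 adjusted over the list alone, camera adjusted p = 4.59e-17, adjusted p = 0.0132 with an estimated correlation), including Lif (−1.18), Tnfsf15 (−0.92) and Osm (−0.52). Of 22 NRF2 targets 12 rose (13 adjusted over the list alone, camera adjusted p = 1.13e-15, adjusted p = 0.0132 with an estimated correlation). These were Gclm, Gsta3 and Gstm1 (0.53), Nqo1 (0.51), Taldo1 (0.46), Cat (0.43), Pgd (0.39), Prdx1 (0.34), Gclc (0.29), Gsr (0.27), Txnrd1 (0.26) and Srxn1 (0.67). The Srxn1 call was kept only without LPS+DHA5HT array 1 or 3 and was lost in the other 6 leave-outs (0.48 to 0.72).

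Among 34 interferon-stimulated genes 7 fell, such as Gbp5 (−1.14), Rsad2 (−0.96), Cmpk2 (−0.76) and Oasl1 (−0.56), with 15 adjusted over the list alone (adjusted p = 1.24e-11, adjusted p = 0.222 with an estimated correlation and 0.0264 with the replicate block added to it). Of 24 NF-kB genes 3 fell, Nfkbiz, the RNA-binding protein gene Zfp36 (−0.48) and Rel (−0.29), with 7 adjusted over the list alone (adjusted p = 2.06e-08, adjusted p = 0.142 with an estimated correlation). The Rel call was lost when any 1 of the 8 LPS and LPS+DHA5HT arrays was left out (−0.31 to −0.25, adjusted p 0.0502 to 0.120). Of 9 nitric oxide and arginine genes 3 fell, Nos2, Slc7a2 (−0.83) and Odc1 (−0.46), with 3 adjusted over the list alone (adjusted p = 0.00044, adjusted p = 0.142 with an estimated correlation). Of 24 chemokines 1 fell, Ccl22 (−1.04, adjusted p = 0.0345), with 5 adjusted over the list alone (list adjusted p = 0.000372, adjusted p = 0.142 with an estimated correlation). Its call was lost without LPS array 1 or 3 or LPS+DHA5HT array 1, 2 or 4 (−1.10 to −0.82). Of 22 antigen presentation genes 2 fell, Cd80 (−0.64) and Cd86 (−0.33), with 4 adjusted over the list alone (adjusted p = 0.00369, adjusted p = 0.153 with an estimated correlation). Cd80 lost its call without LPS array 1, 2 or 4 or LPS+DHA5HT array 1 or 4 (−0.64 to −0.55), and Cd86 without LPS array 2 or LPS+DHA5HT array 4 (−0.30 and −0.29).

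Of 33 cell cycle genes 4 rose, Ccne1 (0.52, adjusted p = 0.00637), Cdc6 (0.45), E2f2 (0.32) and Pcna (0.23), with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00467, adjusted p = 0.634 with an estimated correlation). Cdc6 (0.38 to 0.47) and Pcna (0.20 to 0.24) kept their calls only without LPS array 1 or LPS+DHA5HT array 2, and E2f2 (0.26 to 0.36) only without LPS+DHA5HT array 2. E2f2 also lost it after centring (0.31, adjusted p = 0.0570). The cell cycle list itself lost its call without LPS array 2 or LPS+DHA5HT array 1 or 3 (adjusted p 0.159 to 0.785). Of 21 cholesterol synthesis genes 1 fell, Tm7sf2 (−0.34, adjusted p = 0.0485), with 2 adjusted over the list alone (list adjusted p = 0.00500, adjusted p = 0.492 with an estimated correlation). Tm7sf2 kept its call only without LPS+DHA5HT array 1 (−0.36 to −0.29 in the other 7 leave-outs) and lost it after quantile normalization (adjusted p = 0.0532). The list lost its call without LPS+DHA5HT array 4 (adjusted p = 0.165).

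Some lists passed downward with 0 genes past the limma threshold. They were glycolysis and hypoxia (0 of 23, 2 adjusted over the list alone, 6 at an unadjusted p under 0.05, list adjusted p = 5.69e-05, adjusted p = 0.312 with an estimated correlation), the unfolded protein and integrated stress response (0 of 22, 1 adjusted over the list alone, 2 at an unadjusted p under 0.05, list adjusted p = 0.0153, adjusted p = 0.492 with an estimated correlation) and anti-inflammatory genes (0 of 12, 2 adjusted over the list alone, 3 at an unadjusted p under 0.05, list adjusted p = 0.0434, adjusted p = 0.142 with an estimated correlation). Members that did not pass were the lactate exporter Slc16a3 (−0.32, adjusted p = 0.0523), Ddit4 (−0.61, adjusted p = 0.327) and Il1rn (−0.38, adjusted p = 0.0770). The stress list lost its call without LPS array 2 or LPS+DHA5HT array 1 or 3 (adjusted p 0.0597 to 0.153), and the anti-inflammatory list without LPS array 2, 3 or 4 or LPS+DHA5HT array 1, 3 or 4 (adjusted p 0.0539 to 0.172).

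For genes changed by DHA5HT in LPS-treated cells the count was 337 of 18820, 154 higher and 183 lower. Among all 18820 genes 1484 did not overlap between the groups, where chance gives 2.86%. Only 3 rose at least 2-fold (Serpinb9b, Treml4 and Gsta3), while 30 fell that far. Of the 34 lists 14 passed, 2 upward and 12 downward, and the other 20 had adjusted p values from 0.0917 to 0.846. Centring gave 110 higher and 216 lower, the replicate block 647 genes (323 higher, 324 lower), the filter on dim genes 557, all probe sets 139, and a fit on the compared arrays alone 86. The count was 222, 143, 223 and 177 without LPS array 1, 2, 3 and 4, and 180 and 154 without LPS+DHA5HT array 1 and 4. Without both LPS+DHA5HT array 1 and 4, an alternative chosen after seeing the data, it was 41 (9 higher, 32 lower).

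Genes that DHA5HT lowered in LPS-treated cells were mostly genes that LPS raised. Of the 183 lowered genes 137 (74.9%) were higher with LPS by the main effect, where 30.0 would be shared by chance, and of the 154 raised genes 93 (60.4%) were lower with LPS, where 30.8 would be. Across all 18820 genes, which are not independent replicates, the DHA5HT effect in LPS-treated cells had a Pearson r of −0.365 and a Spearman rho of −0.188 with the LPS main effect, with a slope of −0.129. Among the 6848 genes past the threshold for the LPS main effect r was −0.465 and rho −0.343. Of the 35 splits of the 8 LPS-treated arrays 2 gave a correlation as far from 0 as the real one, the real one included.

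**Figure D2:**
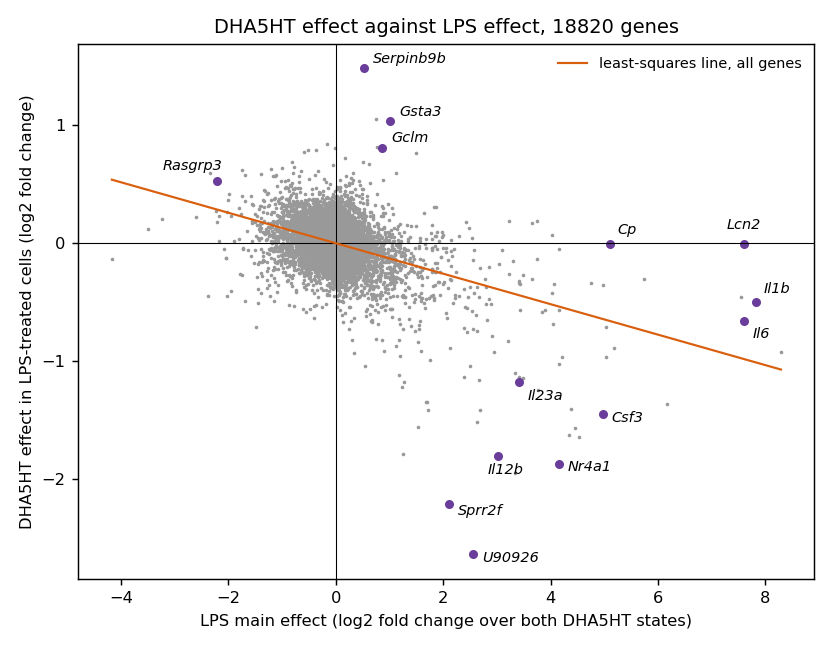
DHA5HT effect in LPS-treated cells (y axis, log2) against the LPS main effect (x axis, log2) for 18820 genes, with named genes labelled. The line is the least-squares fit with a slope of −0.129, so genes raised by LPS lie on balance below 0.

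DHA5HT without LPS asks what the compound did in unstimulated cells. Among the 90 genes that fell were 26 of the 34 measured interferon-stimulated genes, which act in the antiviral response. Irf7 (probe set 10569102), the transcription factor that amplifies type I interferon, fell from 8.91 ± 0.34 (SD, n = 4) to 6.70 ± 0.34 (SD, n = 4), 4.61-fold lower (−2.21, SE 0.17, limma adjusted p = 2.02e-06). Cxcl10, an interferon-induced chemokine gene, fell from 8.12 ± 0.25 to 6.36 ± 0.41 (adjusted p = 3.88e-05). Also lower were Rtp4 (−2.53), Ifi44l (−2.24), Usp18, a brake on interferon signalling (−2.13), the RNA sensor gene Dhx58 (−1.70), Ifit1 (−1.69) and Isg15 (−1.67). In each of these genes all 4 DHA5HT arrays lay below all 4 control arrays.

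Of 34 interferon-stimulated genes 26 fell and 0 rose, with 30 lower adjusted over the list alone and a median change of −0.96 (camera adjusted p = 8.27e-86, adjusted p = 0.0045 with an estimated correlation). Of 22 antigen presentation genes 2 fell, the peptide transporter gene Tap1 (−0.66) and the immunoproteasome gene Psmb8 (−0.28), with 8 adjusted over the list alone (adjusted p = 1.80e-07, adjusted p = 0.0351 with an estimated correlation). Psmb8 kept its call only without control array 1 and lost it in the other 7 leave-outs (−0.30 to −0.25). Of 24 chemokines 3 fell, Cxcl10, Ccl5 (−1.43) and Cxcl2 (−0.93), with 3 adjusted over the list alone (adjusted p = 0.00228, adjusted p = 0.179 with an estimated correlation). Of 24 NF-kB genes 2 fell, Tnfaip3, a brake on NF-kB, (−0.65) and Traf1 (−0.43), with 6 adjusted over the list alone (adjusted p = 1.66e-07, adjusted p = 0.179 with an estimated correlation). Of 9 nitric oxide and arginine genes 1 fell, Acod1, which makes itaconate, (−1.22), with 3 adjusted over the list alone (adjusted p = 0.000219, adjusted p = 0.179 with an estimated correlation).

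The cytokine readouts did not pass in unstimulated cells. Values were −0.12 for Il23a (adjusted p = 0.806), 0.05 for Il12b (0.966), −0.08 for Il6 (0.855), 0.05 for Il1b (0.949), −0.19 for Tnf (0.531) and −0.60 for Nos2 (0.450). In the limma test 0 of 13 IL-23 and IL-12 genes (list adjusted p = 0.279) and 0 of 14 IL-17 family genes (list adjusted p = 0.893) passed, 0 of them adjusted over the list alone, and 1 of each list had an unadjusted p under 0.05. Of 24 IL-17 target genes 3 fell, Ptgs2 (−0.92, adjusted p = 0.00572), Cxcl2 and Tnfaip3, with 4 adjusted over the list alone, which is not independent evidence (list adjusted p = 0.00467, adjusted p = 0.344 with an estimated correlation). Without DHA5HT array 1 the adjusted p of that list was 0.0527. The pro-inflammatory cytokine list passed downward with 0 of 19 genes past the limma threshold and 0 adjusted over the list alone (6 at an unadjusted p under 0.05, list adjusted p = 0.0182, adjusted p = 0.398 with an estimated correlation), and its adjusted p was 0.0621 without control array 2.

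Metabolic and stress lists passed downward with few genes or none. Of 23 glycolysis and hypoxia genes 2 fell, the mitophagy gene Bnip3 (−0.82, adjusted p = 0.0144) and the prolyl hydroxylase gene P4ha1 (−0.45), with 10 adjusted over the list alone (list adjusted p = 1.96e-09, adjusted p = 0.179 with an estimated correlation). Both lost their calls without control array 2 or 4 or DHA5HT array 1 or 2 (Bnip3 −0.79 to −0.72, P4ha1 −0.45 to −0.38). For the unfolded protein and integrated stress response the limma count was 0 of 22 (7 adjusted over the list alone, 11 at an unadjusted p under 0.05, adjusted p = 2.04e-08, adjusted p = 0.172 with an estimated correlation and 0.0141 with the replicate block added to it), with −0.20 for Hsp90b1 and −0.31 for Sdf2l1. For oxidative phosphorylation it was 0 of 30 (0 adjusted over the list alone, 4 at an unadjusted p under 0.05, adjusted p = 0.00422, adjusted p = 0.335 with an estimated correlation).

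Few genes rose. Mrc1, the mannose receptor gene used as a marker of alternative activation, rose from 3.40 to 4.13 (0.72, SE 0.10, adjusted p = 0.000719), values close to the 3.77 of the lymphocyte and epithelial markers. It was the 1 gene that passed of the 19 in the alternative activation list (1 adjusted over the list alone, list adjusted p = 0.0250, adjusted p = 0.179 with an estimated correlation). The list lost its call without control array 2 or 4 or DHA5HT array 3 (adjusted p 0.0715 to 0.0940). Egr4 rose by 0.63, Ms4a6d by 0.58, the transporter gene Abcc3 by 0.55, the selenium carrier gene Selenop by 0.48 and the transferrin receptor gene Tfrc by 0.45. Without DHA5HT array 2 the Tfrc call was lost (0.42, adjusted p = 0.0511). A probe set each of Dpp10 (0.43) and Arhgef5 (0.42, from 3.53 in controls) passed. The other probe set of each gene (−0.07, adjusted p = 0.927, and 0.12, adjusted p = 0.693) lay at means of 3.46 and 3.55, below 3.77, where a change is hard to see. The Arhgef5 probe set that passed had a mean of 3.66, also below 3.77, so its rise is in doubt too.

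In all, 113 of 18820 genes changed, 23 higher and 90 lower, with 24 lower and 0 higher by at least 2-fold. Of all 18820 genes 1108 did not overlap between the groups, where chance gives 2.86%. Of the 34 lists 11 passed, 1 upward and 10 downward, and the other 23 had adjusted p values from 0.0766 to 0.983. Of the 90 lowered genes 82 were higher with LPS by the main effect, where 14.7 would be shared by chance. Across genes the DHA5HT effect without LPS had r = −0.245 and rho = −0.155 with the LPS main effect.

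**Figure D3:**
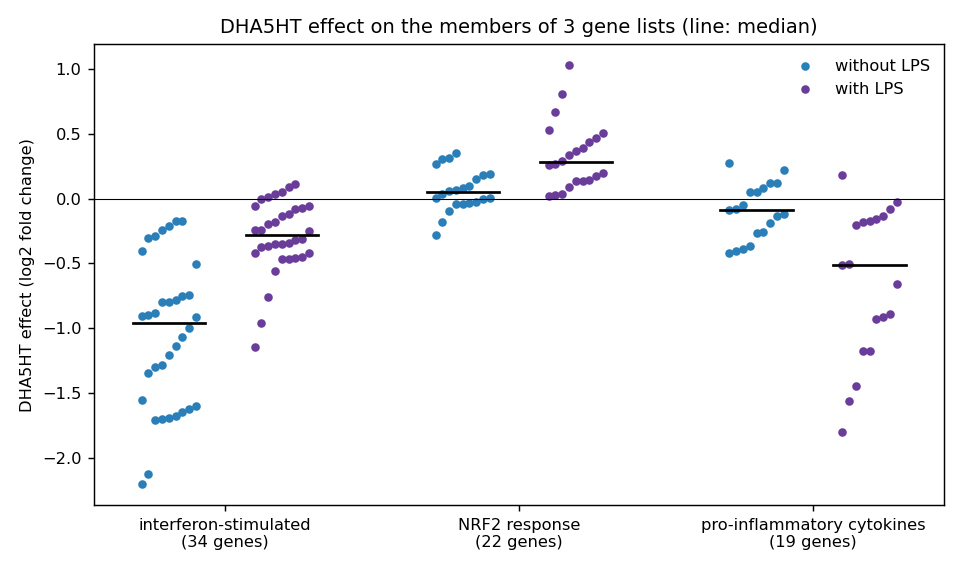
DHA5HT effect (log2) without LPS and with LPS on each measured member of 3 lists: 34 interferon-stimulated genes, 22 NRF2 targets and 19 pro-inflammatory cytokines. Points are genes and lines are medians, which for the interferon list are −0.96 without LPS and −0.28 with LPS.

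The difference between the DHA5HT effects with and without LPS tests whether the compound acted differently in stimulated cells. The differences (with LPS minus without) were negative for the IL-23 subunit genes and positive for interferon genes. The value was −1.85 (SE 0.26, limma adjusted p = 0.00228) for Il12b and −1.06 (SE 0.16, adjusted p = 0.00542) for Il23a. In control cells these genes lay at 4.30 and 4.70, too close to 3.77 for decreases of the size seen with LPS to appear, so the differences do not show that DHA5HT acted otherwise on them without LPS. For interferon genes lowered without LPS the differences were 2.03 (SE 0.24, adjusted p = 0.000884) for Irf7, 1.23 for Dhx58, 1.37 for Ifit1 and 1.34 for Oas2. No difference passed for Il6 (−0.58, adjusted p = 0.152), Tnf (0.02, adjusted p = 0.991), Nos2 (−0.42, adjusted p = 0.847), Cxcl10 (1.08, adjusted p = 0.135), Ptgs2 (0.77, adjusted p = 0.257), Csf3 (−1.57, adjusted p = 0.0544) or Gsta3 (0.76, adjusted p = 0.257).

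Of the 34 interferon-stimulated genes 15 had a positive difference past the threshold (24 positive and 1 negative adjusted over the list alone, list median 0.78, camera adjusted p = 6.69e-40, adjusted p = 0.0581 with an estimated correlation). With the replicate block added, the last value was 0.000895, while those of the NRF2 and pro-inflammatory cytokine lists were 0.104 each. Of 22 NRF2 targets 0 passed in limma (3 positive adjusted over the list alone, 10 at an unadjusted p under 0.05), and the list passed upward (adjusted p = 1.64e-09, adjusted p = 0.0581 with an estimated correlation). Of 19 pro-inflammatory cytokines 2 passed, Il12b and Il23a (10 negative and 1 positive adjusted over the list alone, adjusted p = 1.64e-09, adjusted p = 0.0581 with an estimated correlation). The same 2 genes passed of the 13 in the IL-23 and IL-12 list (3 adjusted over the list alone, not independent evidence, adjusted p = 0.000209, adjusted p = 0.233 with an estimated correlation). Of 18 p53 and apoptosis genes 2 passed, Bcl2, which blocks apoptosis, (−0.62, adjusted p = 0.0262) and Bbc3, which promotes it, (−0.59, adjusted p = 0.0331), with 4 negative and 1 positive adjusted over the list alone (list adjusted p = 0.0486, adjusted p = 0.119 with an estimated correlation). Of 14 osteoclast markers 0 passed in limma (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, list adjusted p = 0.0486, adjusted p = 0.135 with an estimated correlation). The p53 list kept its call only without control array 1 or 3, DHA5HT array 2 or 4 or LPS+DHA5HT array 2 or 4, and had adjusted p values from 0.0512 to 0.112 without each of the other 10 arrays. The osteoclast list lost its call without control array 1 or 3, DHA5HT array 2 or 3, LPS array 2 or 3 or LPS+DHA5HT array 3 (adjusted p 0.0591 to 0.172). Bbc3 kept its call only without control array 2 or 4, DHA5HT array 2, LPS array 3 or LPS+DHA5HT array 1 or 4 (−0.61 to −0.53 without each of the others). Bcl2 lost its call without DHA5HT array 1, 2 or 3, LPS array 1, 2 or 4, control array 3 or LPS+DHA5HT array 4 (−0.62 to −0.59).

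For genes whose DHA5HT effect differs with LPS the count was 62 of 18820, 31 positive and 31 negative. Of the 34 lists 6 passed with camera at the preset correlation, 4 passed with fry and 0 with an estimated correlation (6 at an unadjusted p under 0.05), and the other 28 had adjusted p values from 0.0721 to 0.994. The count was 35 without DHA5HT array 1, 37 and 34 without LPS array 1 and 2, 41 without control array 2 and 28 over all probe sets. Without LPS+DHA5HT array 1 and 4 together it was 36 (22 positive, 14 negative).

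DHA5HT effects in the presence and absence of LPS overlapped in part. Of the genes changed in either setting 10 fell in both, where 0.875 would by chance if every gene were equally likely to be called: Cmpk2, Daxx, Dhx58, Gbp3, Ifih1, Oasl1, P4ha2, Rnf31, Rsad2 and Slc39a10. Most lowered genes of each setting were higher with LPS by the main effect (82 of 90 and 137 of 183), so chance alone gives a larger overlap than 0.875. Another 3 rose in both (Rasgrp3, Sfxn5 and Twf1, 0.188 by chance), and 0 of the genes past the limma threshold in both went in opposite directions (0.736 and 0.224 by chance). Across genes the DHA5HT effects had r = 0.262 and rho = 0.237. Without LPS, Sfxn5 kept its call only without control array 1 or DHA5HT array 4 (0.35 to 0.44 without each of the others). Daxx, Ifih1, P4ha2, Rnf31, Slc39a10 and Twf1 were named after their values were seen.

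Several lists passed in none of the 4 comparisons. Their lowest adjusted p values were 0.204 for Toll-like receptor sensing, 0.121 for chemokine receptors, 0.464 for the prostaglandin and leukotriene pathway, 0.488 for the endocannabinoid and serotonin pathway, 0.611 for PPAR targets, 0.0766 for LXR targets, 0.178 for lysosome and scavenger receptors, 0.127 for macrophage identity, 0.709 for dendritic cells, 0.301 for fibroblasts, 0.236 for lymphocytes, 0.353 for epithelial cells and 0.381 for ribosomal proteins. The IL-17 family list had 0.454.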

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

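The tests of RNA from LPS-treated samples, of an equal loss of the response, of the array with conflicting labels and of a weaker LPS response were chosen after the results they measure had been seen; the test of single arrays and the splits were chosen before.

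The first pattern is the decrease of interferon-stimulated genes with DHA5HT in unstimulated cells. RNA carried over from LPS-treated samples into the controls would bring the genes that LPS raised most, yet the 12 largest stood in controls at a median of 1.37% of their LPS level on the linear scale (highest 2.69%), while the list lost a median of 18.1% of its LPS level (lower quartile 8.85%). Open are a difference in vehicle or handling that affected all 4 arrays of a group, which cannot be told apart from the treatment, and, as a biological hypothesis, that DHA5HT may lower interferon signalling in resting cells. The list median of the difference between the DHA5HT effects (with LPS minus without) was 0.78, with camera adjusted p = 0.0581 with an estimated correlation. With the replicate block added, that adjusted p was 0.000895. The labels do not settle whether the arrays are paired by number.

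The second pattern is the decrease of LPS-induced cytokine genes with DHA5HT. An equal proportional loss of the response in every gene would spread the shares of the log2 response lost no more than their errors, but over 45 LPS-induced genes of like brightness the variance was 6.28 times that expected (median lost 17.0%, quartiles 8.64% and 25.2%), with 45.6% ± 4.57 (SE) for Il12b and 30.0% ± 2.94 for Il23a against 0.0929% ± 2.06 for Cp, the ceruloplasmin gene. The array with conflicting labels does not carry the pattern: without it Il12b was at −1.78 (adjusted p = 0.000408 in limma) and Il23a at −1.09 (adjusted p = 0.000157). That this array had no LPS is argued against by its position of 83.8% between control and LPS. Open are a weaker LPS stimulus that genes follow unequally, vehicle or handling shared by a group, and, as a biological hypothesis, that DHA5HT may act on some LPS-induced genes, IL-23 among them, more than on others.

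The third pattern is the increase of NRF2 targets with DHA5HT in LPS-treated cells. A weaker LPS response would lower the members that LPS raised, but these had a median change of 0.197, and 9 of 9 were higher (4 past the threshold). This covers only members that LPS raised. For Gclc, Pgd and Taldo1, which LPS lowered and which rose with DHA5HT, a weaker LPS response stays open. A single array is argued against by the leave-outs, in which the list median stayed between 0.257 and 0.308. Vehicle or handling shared by a group stays open, and so does the biological hypothesis that DHA5HT may activate the NRF2 response in these cells. Whether it does so only with LPS is undecided, since the list median of 0.25 for the difference between the DHA5HT effects had adjusted p = 0.0581 with an estimated correlation.

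Other lists that passed for the difference between the DHA5HT effects at the preset correlation had medians of −0.56 (pro-inflammatory cytokines), −0.17 (IL-23 and IL-12 family), −0.12 (p53 targets) and −0.13 (osteoclast markers) for the effect with LPS minus that without. With an estimated correlation none of these 4 passed (adjusted p = 0.0581, 0.233, 0.119 and 0.135 with an estimated correlation), and the p53 and osteoclast lists lost the call in 10 and 7 of 16 leave-outs. Of the pro-inflammatory cytokines, Il6 and Il1a lay below 3.77 without LPS, where a decrease could not be seen. In all, 62 genes differed, and those named in the text had the following differences. Negative ones were U90926 −2.51, Cstdc4 −2.07, Sprr2f −2.04, Sprr2e −1.96, Il12b −1.85, Nr4a3 −1.80, Sprr2d −1.69, Csn1s1 −1.50, Mmp13 −1.45, Il23a −1.06, Ms4a6d −0.79, Mrc1 −0.72, Bcl2a1c −0.71, Bcl2 −0.62 and Bbc3 −0.59. Without LPS the means of U90926, Sprr2e, Sprr2d, Nr4a3 and Csn1s1 lay below the 3.77 of genes these cells should lack, and those of Sprr2f, Il12b and Il23a were at 3.88, 4.30 and 4.70 in controls, so that decreases of the size seen with LPS could not appear there. In the same way Mrc1 lay at 3.12 and 3.13 in the LPS-treated groups, where a small rise could not be seen. These differences do not show that DHA5HT acted otherwise in one state than in the other. Positive ones were Rtp4 2.49, Ifi44l 2.14, Irf7 2.03, H2-T24 1.93, Usp18 1.76, Oasl2 1.64, Ifit1 1.37, Isg15 1.37, Oas2 1.34, Dhx58 1.23, Gbp7 0.96 and Cmpk2 0.95. The Mmp13 difference kept its call only without LPS array 4 or LPS+DHA5HT array 2 (−1.54 to −1.25 without each of the others).

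Single arrays lay far from the other 3 of their group in 43 of 804 gene and group sets (Dixon's test at 95%), where chance gives 40.2. Their log2 values in the control group were Il1r2 5.66 (array 1), Pgd 11.27 (array 2), Dhcr7 10.78, Psat1 10.81, Il10ra 8.99 and Gbp5 3.63 (array 3), and Abcc1 9.45, Mgst1 5.67, Ifi44l 7.46, H2-T24 7.67 and Car2 9.27 (array 4). In the DHA5HT group they were Ccl4 9.71 and Cxcl3 4.15 (array 1), St8sia4 9.48, Slc14a1 6.78, Ebi3 9.28 and Gstm1 9.50 (array 2), Asns 11.07, Rgs18 8.88 and Nfkb2 9.20 (array 3), and Nr4a1 5.01 and Car2 9.02 (array 4). In the LPS group they were Slc22a18 5.56, Mrc1 3.26 and Ifi27 7.50 (array 1), Ebi3 10.48, Idh2 9.66 and Tnf 12.17 (array 2), and Tgfbi 6.45, Sqle 10.425 and Psmb8 10.65 (array 3). In the LPS+DHA5HT group they were Gbp2 9.61 and Inhba 8.74 (array 2), Cd40 8.58, Selenop 7.29 and Ccr6 3.24 (array 3), and Serpinb2 8.20, Ak8 6.33, Slc40a1 8.81, Cxcl3 4.14, Dpp10 3.99, Manf 8.71 and Psmb8 10.47 (array 4).

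Of 12457 probe sets that the gene table does not name, 1153 changed with LPS (455 higher, 698 lower), 9 with DHA5HT in LPS-treated cells (4 higher, 5 lower) and 15 with DHA5HT without LPS (2 higher, 13 lower), tested as the other probe sets were. Of 1881 probe sets that name several genes 414, 4 and 8 changed.

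Other splits of the same arrays give a rough measure of what chance can produce. With 35 splits the share cannot fall below 1 of 35. Splits that mix conditions also put the difference between them into the spread, which holds down the number of genes called. A low share alone therefore does not exclude chance. The share was under the bound for the genes changed by LPS (5346, highest of the other splits 0). There 1 of 35 was as large, with the real one included. So it was for the genes changed by DHA5HT in LPS-treated cells (337, highest other 19, 1 of 35). The genes changed by DHA5HT without LPS met it too (113, highest other 1, 1 of 35). The mixed splits hold down the other counts, so the splits cannot exclude chance for these genes. The share was also under the bound, by narrow margins, for the lists with LPS (16, highest other 14, 1 of 35) and the lists with DHA5HT without LPS (11, highest other 10, 1 of 35). So it was for the genes whose DHA5HT effect differs with LPS (62, highest other 60, 1 of 100 groupings with the real one included). The bound was not met for the lists with DHA5HT in LPS-treated cells (14, highest other 14, 2 of 35), for the lists in the difference between the DHA5HT effects (6, highest other 15, 39 of 100) and for the correlation across genes between the LPS main effect and the DHA5HT effect in LPS-treated cells (−0.365, farthest other 0.396, 2 of 35).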

How the results depend on the processing

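Leaving out LPS+DHA5HT arrays 1 and 4 together was chosen after the results had been seen; the other alternatives were chosen before. Of 176 gene calls named by the rule, 0 changed direction in 2184 recomputed limma values, 160 of 1480 leave-one-out values were no longer past the threshold (29 calls lost at least once, fewer arrays being tested) and 7 of 704 in other settings. Most lost calls stand beside their genes above. Besides these, the calls of Ak8, Cd1d1, Mfsd6, Rgs18, Slc22a18 and Slc40a1 with DHA5HT in LPS-treated cells were lost in 3, 2, 2, 6, 6 and 7 of 8 leave-outs, and those of Ifi27 and Sfxn5 without LPS in 6 each. Slc40a1 also lost its call after quantile normalization and centring (0.76 and 0.75, adjusted p = 0.0545 and 0.0562). Intensities near 3.77, the level of genes these cells should lack, limit what can be seen for dim genes.

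The replicate block gave 5757 genes with LPS, 647 (323 higher, 324 lower) with DHA5HT in LPS-treated cells, 179 (56 and 123) without LPS and 96 (49 and 47) for the difference, of which 5283, 336, 111 and 60 were genes called without it; 16, 13, 11 and 6 lists passed and the correlation was −0.365. Ifi27 lost its call with the block (0.47, adjusted p = 0.0780). With the block and an estimated correlation the interferon list passed also with LPS (adjusted p = 0.00257), with DHA5HT in LPS-treated cells (0.0264) and for the difference (0.000895), and the stress response list with DHA5HT without LPS (0.0141), against 0.0566, 0.222, 0.0581 and 0.172 without the block. Same-numbered arrays of different groups had deviations that correlated by 0.0699 to 0.232 over 24 pairs, not all above 0.1, with a median of 0.129 against −0.0635 for arrays of different number. Over the brighter genes the range was 0.145 to 0.464, all above 0.1, and 15 of 16 arrays correlated best with their own number. This is a hint from the data that the numbers mark something shared, of which the labels say nothing. Arrays 1 and 3, and arrays 2 and 4, also resembled each other across groups. Their median was 0.0573, against −0.0971 for the other pairs of different number.

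The filter on dim genes gave 557 genes (288 and 269) with DHA5HT in LPS-treated cells, all probe sets 139 (44 and 95) there and 28 (16 and 12) for the difference, and a fit on the compared arrays alone 86 (13 and 73); fewer or more tests, or fewer residual degrees of freedom, enter by construction. Unadjusted p under 0.01 gave 1072, 599 and 432 genes with DHA5HT in LPS-treated cells, without LPS and for the difference, and an absolute log2 change of at least 1 gave 631 with LPS, 33, 24 and 30, both by construction. Without LPS+DHA5HT arrays 1 and 4 the counts were 41 and 36. Leaving out 1 array of the compared groups gave 4844 to 5081 genes with LPS, 143 to 289 with DHA5HT in LPS-treated cells, 83 to 116 without LPS and 34 to 62 for the difference. All other settings kept these counts within 1.5 times.

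The correlation was −0.465 in LPS-responsive genes, −0.407 with the filter on dim genes, −0.188 by Spearman, −0.368 with the LPS arrays halved, and −0.396 to −0.292 with 1 LPS-treated array left out (−0.292 without LPS+DHA5HT array 1); the cause was not tested. With an estimated correlation 6, 2, 2 and 0 lists passed in the order above, against 16, 14, 11 and 6, and with fry 22, 9, 5 and 4; the cause was not tested. With 1 array of the compared groups left out 14 to 16, 11 to 15, 9 to 13 and 4 to 9 lists passed.

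Some values that never passed changed sign with 1 array left out; the cause was not tested. For Il12b without LPS (0.05, range −0.0188 to 0.13) they were −0.0174, −0.0188 and −0.0130 without control 1, DHA5HT 3 and control 4, and for Il1b without LPS (range −0.0698 to 0.14) −0.0698 and −0.0609 without control 3 and DHA5HT 3. Il10 without LPS ranged from −0.18 to 0.00419 (without DHA5HT 3). Ccl20 without LPS ranged from −0.00652 (without control 4) to 0.14, and in LPS-treated cells from −0.14 to 0.0607, with 0.0607, 0.0118 and 0.0401 without LPS 2, LPS+DHA5HT 3 and 4. The Tnf difference ranged from −0.0476 to 0.098 and was −0.0157, −0.0476, −0.0450, −0.0199, −0.00616 and −0.000836 without LPS 1, LPS+DHA5HT 2, control 3, LPS 3, DHA5HT 4 and LPS 4.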

Other observations

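The gene families below were chosen after their values had been seen; the test of the hypothesis was fixed before its outcome was.

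Some immediate early genes fell with DHA5HT in LPS-treated cells, namely the nuclear receptor genes Nr4a1 and Nr4a3 (−1.87 and −1.78) and the transcription factor gene Egr1 (−0.89, limma adjusted p = 0.0199). Nr4a2 (−0.17, adjusted p = 0.457), Egr2 (−0.37, adjusted p = 0.193), Egr3 (−0.16, adjusted p = 0.572) and Egr4 (0.03, adjusted p = 0.937) did not pass, and no difference between these genes was tested. Nr4a3 stood at 3.27 in LPS+DHA5HT arrays, below the 3.77 of genes these cells should lack. The cornified envelope genes Sprr2d, Sprr2e, Sprr2f, Sprr2g, Sprr2h and the pseudogene Sprr2j-ps rose with LPS (5.19, 4.31, 3.14, 3.97, 2.18 and 1.63, lower bounds for all but Sprr2f, since the other control means lay below 3.77) and were lower with DHA5HT (−1.63, −1.95, −2.21, −1.13, −0.99 and −0.96), while Sprr2a1 had −0.33 (adjusted p = 0.308). The members are nearly identical in sequence, so probe sets of the family can share signal and are not counted here as separate findings.

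Among glutathione transferases Gsta3, Gstm1 and Gstm3 rose with DHA5HT in LPS-treated cells (1.03, 0.53 and 0.49), while Gsta4 (−0.02, adjusted p = 0.967), Gstm2 (0.05, adjusted p = 0.921) and Gstm4 (0.04, adjusted p = 0.917) did not pass. Other genes that changed there were the lipid sensor Trem2 (0.57), the cholesterol exporter Abca1 (−0.73), the scavenger receptor Marco (−0.96), the thromboxane synthase gene Tbxas1 (0.47) and the leukotriene pathway gene Alox5ap (0.27). The zinc importer Slc39a10 was lower with DHA5HT both with LPS (−0.53) and without (−0.43).

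A hypothesis was a DHA5HT effect shared by both states. The DHA5HT effects with and without LPS had r = 0.262 across genes. Of 100 groupings, the real one included, 2 were as far from 0 (farthest other −0.273), which met the bound set for it. Both effects also ran against the LPS main effect (r = −0.365 with LPS and −0.245 without). Whether the correlation goes beyond that was not tested. A vehicle or handling difference shared by the DHA5HT groups cannot be told apart from the compound.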
